A study of Mus musculus with 4 samples.

How the data were processed

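Zygotene spermatocytes of 2 Control and 2 Dhx36 cKO samples were profiled by RNA-seq of ribosomal RNA-depleted total RNA with a directional library kit, per the labels. The labels put the purity of the sorted cells at about 95% in the extraction notes and at 95% to 98% in the treatment notes. They do not say whether replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

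The deposited table holds raw read counts per Ensembl gene. The submitters' processing notes name FastQC 0.11.9, Trim Galore 0.6.7, HISAT2 2.2.1, featureCounts and Subread 2.0.3, and the genome build mm9. Because some gene identifiers belong to later annotation releases than that build, no coordinates are printed. The strand setting and the treatment of multi-mapped reads are not given in the sources used here, so counts of antisense and overlapping genes are uncertain. Of 55357 gene identifiers 52081 matched a name in GENCODE M21, which served for names, chromosomes, neighbour order and transcript properties, and 3276 did not match, 216 of them among the tested genes.

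Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr, which left 18804, libraries were scaled by TMM, and groups were compared with the quasi-likelihood F test without a replicate block, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 2 residual degrees of freedom. Values in CPM are TMM-scaled. A count of 3, the floor used for absence, is 0.129 to 0.153 CPM in these libraries; this covers counting error only. Total counts ran from 19643829 to 23310512.

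The comparisons, tests, gene lists and rule for naming genes were fixed before the data were examined. Named genes are Dhx36; the 10 genes with the largest rise and the 10 with the largest fall among called genes whose groups do not overlap, with a mean of at least 1 CPM and no predicted, clone-based or pseudogene name; up to 4 members of smallest p in each list, at a mean of at least 1 CPM; and the 2 most abundant members of each marker list. A result for 1 gene under this rule is not reported here. Plau was named beyond this rule, after its values were seen, to complete a list of 4 genes. Of 24 lists, 23 had at least 5 tested members and were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01. The same lists were tested with an estimated correlation and with fry, which tests whether the genes of a list move, on balance, one way.

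The steps were tested on simulated counts for this comparison with 18804 genes, 200 of them changed. The edgeR test recovered 35.8% of 67 genes changed 1.5-fold, 71.6% of 67 changed 2-fold and 90.9% of 66 changed 3-fold, and called 9 unchanged genes. With no gene changed it called 0, as did DESeq2 and limma-voom. A simulated list of 50 genes raised 1.3-fold was called by camera with the preset correlation. It had adjusted p = 0.262 with an estimated correlation and p = 0.0717 with fry, so both of these tests missed it. With so few libraries, a call lost under either test therefore does not show that a list is unchanged. The simulated genes were drawn independently, with the same spread in both groups. These runs therefore do not test errors from correlated genes or from groups of unequal spread.

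Alternatives were DESeq2 1.42.0, limma-voom, RLE factors, library totals alone, no filter, a filter at a mean of 1 CPM, a replicate block, GC correction with and without the block, leaving out the 20 most abundant genes, leaving out each library in turn, and other thresholds. Counts of list members without Dhx36 cKO replicate 1 were added after its collagen counts were seen, and the gene lists, list medians and percentiles of the ribosomal protein and 5' TOP lists in the closing section were computed without each library in turn after their results were seen. The estimated correlation was also used in the fits with 1 library left out, chosen after those fits were seen. Random lists numbered 10000 and intervals are at 95%. Intervals of list medians resample the genes of a list, which are not independent, and hold no spread between libraries.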

Results

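RNA was measured in zygotene spermatocytes, the cells of meiotic prophase in which homologous chromosomes begin to pair, from mouse testes in which spermatogenesis had been synchronised. Pups aged 2 days were fed a blocker of retinoic acid synthesis at 100 μg/g for 7 days, were given retinoic acid at 33 μg/g and were left for 216 h before the cells were sorted on Hoechst fluorescence. The 2 Control libraries were compared with 2 Dhx36 cKO libraries, in which floxed Dhx36 is deleted by a Cre recombinase expressed from the Stra8 locus. The Control samples are wild type per the labels, so the deletion is not separated from the Cre and floxed alleles. DHX36 is a DEAH-box helicase that unwinds G-quadruplexes, the four-stranded folds of guanine-rich DNA and RNA. The totals were 23310512 and 19643829 counts for Control replicates 1 and 2, and 20996362 and 21115194 counts for Dhx36 cKO replicates 1 and 2. The Control pair had a Pearson correlation of log2 CPM (counts scaled to library size) of 0.992 over genes and the Dhx36 cKO pair 0.982; genes are not independent replicates. Counts of the Control pair differed by 4.84 times the sampling variance per gene and those of the Dhx36 cKO pair by 28.6 times, so no pair of libraries was a duplicate.

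Dhx36 (ENSMUSG00000027770) was lower in both Dhx36 cKO libraries. It stood at 145 and 144 CPM in the Control libraries and at 71.0 and 68.1 CPM in the Dhx36 cKO libraries. The log2 fold change was −1.06 (SE 0.08, edgeR adjusted p = 0.0076). The value sums reads over the whole gene and cannot tell deleted exons from retained ones.

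Of 18804 genes tested, 513 rose and 330 fell in Dhx36 cKO cells. Gadd45a, a DNA damage-inducible growth arrest gene, rose from 3.64 and 4.13 CPM to 14.5 and 18.5 CPM (log2 fold change 2.09, SE 0.20, edgeR adjusted p = 0.00969). Pmaip1, which encodes the pro-apoptotic BH3-only protein NOXA, rose by a log2 fold change of 2.03 (SE 0.26). The largest rises and falls given next are those under the naming rule, at a mean of at least 1 CPM. The other genes with the largest rises were Myocos at 2.46, Slc7a9 at 2.14, Cd79a at 2.10, Atp2b2 at 1.92, Slc35d3 at 1.87, Fgf18 at 1.81, Fam19a5 at 1.81 and Dusp2 at 1.78 on the log2 scale. The largest falls were those of Crisp2, a sperm acrosome and tail protein gene, at −2.16 (SE 0.43), Wnt8a at −2.14 and the cadherin gene Cdh26 at −2.06. Myh4 at −1.87, Mlph at −1.83, Clec18a at −1.64 and Il9r at −1.60 fell as well, as did the clustered gamma protocadherin genes Pcdhga4 at −1.85, Pcdhgb1 at −1.84 and Pcdhga1 at −1.57, whose counts are uncertain because their transcripts share exons. Apart from Gadd45a and Pmaip1, the genes named for their rise were low, with no library above 8.24 CPM. The genes named for their fall were low as well, with no library above 7.72 CPM. The change was at least 2-fold in 147 of the genes that rose and 110 of those that fell.

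**Figure D1:**
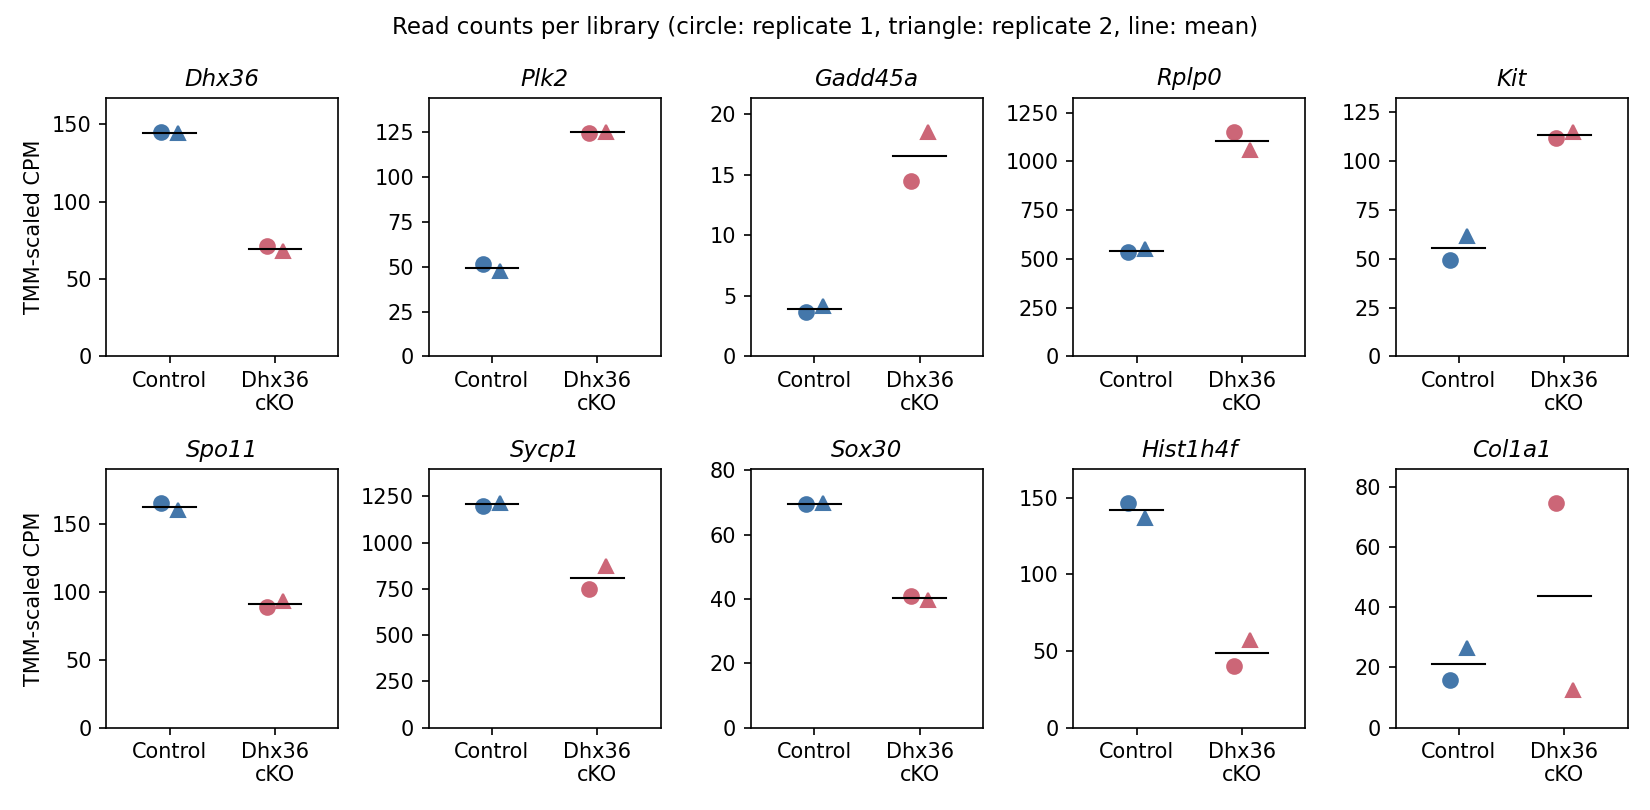
Points show TMM-scaled CPM in each library for 10 genes, with circles for replicate 1, triangles for replicate 2 and lines for group means (n = 2 per group); each vertical axis is linear and starts at 0. Dhx36 sits at 145 and 144 CPM in Control and at 71.0 and 68.1 CPM in Dhx36 cKO, while Col1a1, which was not called, is high in Dhx36 cKO replicate 1 alone at 74.6 CPM.

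These numbers rest on the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment; 5000 genes had an unadjusted p under 0.05, against 940 expected by chance. Without Control replicate 1 the test called 14 genes higher and 7 lower, without Control replicate 2 it called 36 and 16, without Dhx36 cKO replicate 1 it called 3132 and 2562, and without Dhx36 cKO replicate 2 it called 3048 and 2832. The fit without Dhx36 cKO replicate 1 tested 19504 genes, and the Control pair alone measured its spread. Counts of list members given below for that fit rise with its totals and do not measure a stronger effect. With library totals alone in place of TMM, 349 genes were higher and 412 lower, so the share of higher genes was 45.9% rather than 60.9%.

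Cytosolic ribosomal protein genes were higher as a group. Of 87 tested members 17 rose, 0 fell and 70 did not pass the test, and 76 had a log2 fold change above 0. Rplp0, which encodes a stalk protein of the large subunit, rose from 535 and 550 CPM to 1152 and 1059 CPM (log2 fold change 1.03, SE 0.09). Rps2 rose by 0.66, Rps4x by 0.97 and Rps14 by 0.47 on the log2 scale. The list had a median log2 fold change of 0.36 and a camera adjusted p = 1.41e-07, and adjusted p = 0.894 with an estimated correlation. Adjusted over the list alone, 35 members were higher and 2 lower. Without Dhx36 cKO replicate 2 the median was 0.19, and without Dhx36 cKO replicate 1, which carried more collagen RNA, it was 0.449. Ribosomal protein genes have many near-identical pseudogenes, and how multi-mapped reads were counted is not given in the sources used here, so their counts are uncertain.

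Targets of the transcription factor p53 and genes of the integrated stress response, the ATF4-driven programme for amino acid and protein stress, were higher. Among 20 tested p53 targets 3 rose and 0 fell: Plk2, a Polo-like kinase gene, from 51.3 and 47.8 CPM to 125 CPM in both Dhx36 cKO libraries (log2 fold change 1.33, SE 0.09), Phlda3 at 1.58 and Pmaip1 at 2.03. Among 19 tested integrated stress response genes 4 rose and 0 fell: Ddit4 at 1.31, the stress sensor gene Sesn2 at 0.80, the amino acid transporter gene Slc7a5 at 0.69 and the mitochondrial folate enzyme gene Mthfd2 at 0.63. Adjusted over the list alone, 6 members of each list were higher and 0 lower. The p53 list had a median of 0.50 and a camera adjusted p = 0.00776, with adjusted p = 0.894 with an estimated correlation. Fry called it higher (adjusted p = 0.0235). The other lists that camera called were not called by fry (adjusted p from 0.2175 to 0.5415). The stress response list had a median of 0.31 and a camera adjusted p = 0.0308, with adjusted p = 0.894 with an estimated correlation. Without Dhx36 cKO replicate 1 the p53 median was 0.31, with 6 members higher and 1 lower. The stress response median was 0.59 with a filter at a mean of 1 CPM (adjusted p = 0.00724). Its call was lost without Control replicate 2 (median 0.37, adjusted p = 0.0661), without Dhx36 cKO replicate 1 (median 0.21, adjusted p = 0.0972; 7 members higher and 1 lower), with GC correction (median 0.34, adjusted p = 0.0834) and with GC correction and the replicate block together (median 0.23, adjusted p = 0.0921).

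Genes that switch on at the start of pachytene, the stage after zygotene, were lower. Of 27 tested members 4 fell and 0 rose. Sox30, a transcription factor gene, fell from 69.5 and 69.9 CPM to 41.0 and 39.5 CPM (log2 fold change −0.79, SE 0.09), Pdha2, the testis form of a pyruvate dehydrogenase subunit, by 0.97, Zpbp by 0.51 and Zfp541 by 0.47 on the log2 scale. The list had a median of −0.32 and a camera adjusted p = 0.0203, with adjusted p = 0.894 with an estimated correlation; adjusted over the list alone, 3 members were higher and 5 lower. The call was lost without Dhx36 cKO replicate 2 (median −0.23, adjusted p = 0.0914), and without Dhx36 cKO replicate 1, 4 members rose and 14 fell.

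Meiotic recombination genes included 2 that fell and 0 that rose among 36 tested. Spo11, whose product makes the double-strand breaks that start recombination, fell from 166 and 160 CPM to 88.8 and 93.1 CPM (log2 fold change −0.84, SE 0.08), and Mcmdc2 by 0.64 on the log2 scale. Msh4 at −0.40 did not pass the test. Sycp1, the transverse filament of the synaptonemal complex, fell from 1200 and 1214 CPM to 748 and 873 CPM (log2 fold change −0.57, SE 0.10) and was the 1 called member of the 20 on the synaptonemal complex, axis and telomere attachment list. That list was not called (median −0.07, camera adjusted p = 0.423), and adjusted over the list alone 0 members were higher and 1 lower. It was called lower without Dhx36 cKO replicate 2 (median −0.43, adjusted p = 0.00166, and adjusted p = 0.686 with an estimated correlation). Without Dhx36 cKO replicate 1 its median was 0.16. The recombination list had a median of −0.12 and a camera adjusted p = 0.0372, with adjusted p = 0.894 with an estimated correlation; adjusted over the list alone, 0 members were higher and 5 lower. Its call was lost without any 1 of Control replicate 1 (median −0.10, adjusted p = 0.0906), Control replicate 2 (median −0.13, adjusted p = 0.0822) and Dhx36 cKO replicate 1, where the median turned to 0.02 (adjusted p = 0.623; 13 members rose and 8 fell). The median was −0.35 without Dhx36 cKO replicate 2. The call was lost with GC correction (median −0.060, adjusted p = 0.201), with no filter on low counts (median −0.11, adjusted p = 0.0789), with the replicate block (median −0.15, adjusted p = 0.0505) and with the block and GC correction together (median −0.076, adjusted p = 0.189) as well.

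Replication-dependent histone genes, whose mRNAs lack poly(A) tails, were lower. Of 61 tested members 5 fell and 1 rose. Hist1h4f fell from 147 and 137 CPM to 40.3 and 57.0 CPM (log2 fold change −1.55, SE 0.16), Hist1h1d by 1.32, Hist1h4h by 1.16 and Hist1h4i by 1.05 on the log2 scale. Summed over the list, counts were 4218 and 4072 CPM in Control and 2298 and 3383 CPM in Dhx36 cKO. The median was −0.40 with a camera adjusted p = 0.0203, and adjusted p = 0.894 with an estimated correlation; adjusted over the list alone, 6 members were higher and 17 lower. Without Dhx36 cKO replicate 1 the median was −0.13 and the call was lost (adjusted p = 0.135), with 10 members higher and 19 lower. With a filter at a mean of 1 CPM the median was −0.26. Histone genes of one class are near-identical, so their single counts are uncertain.

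**Figure D2:**
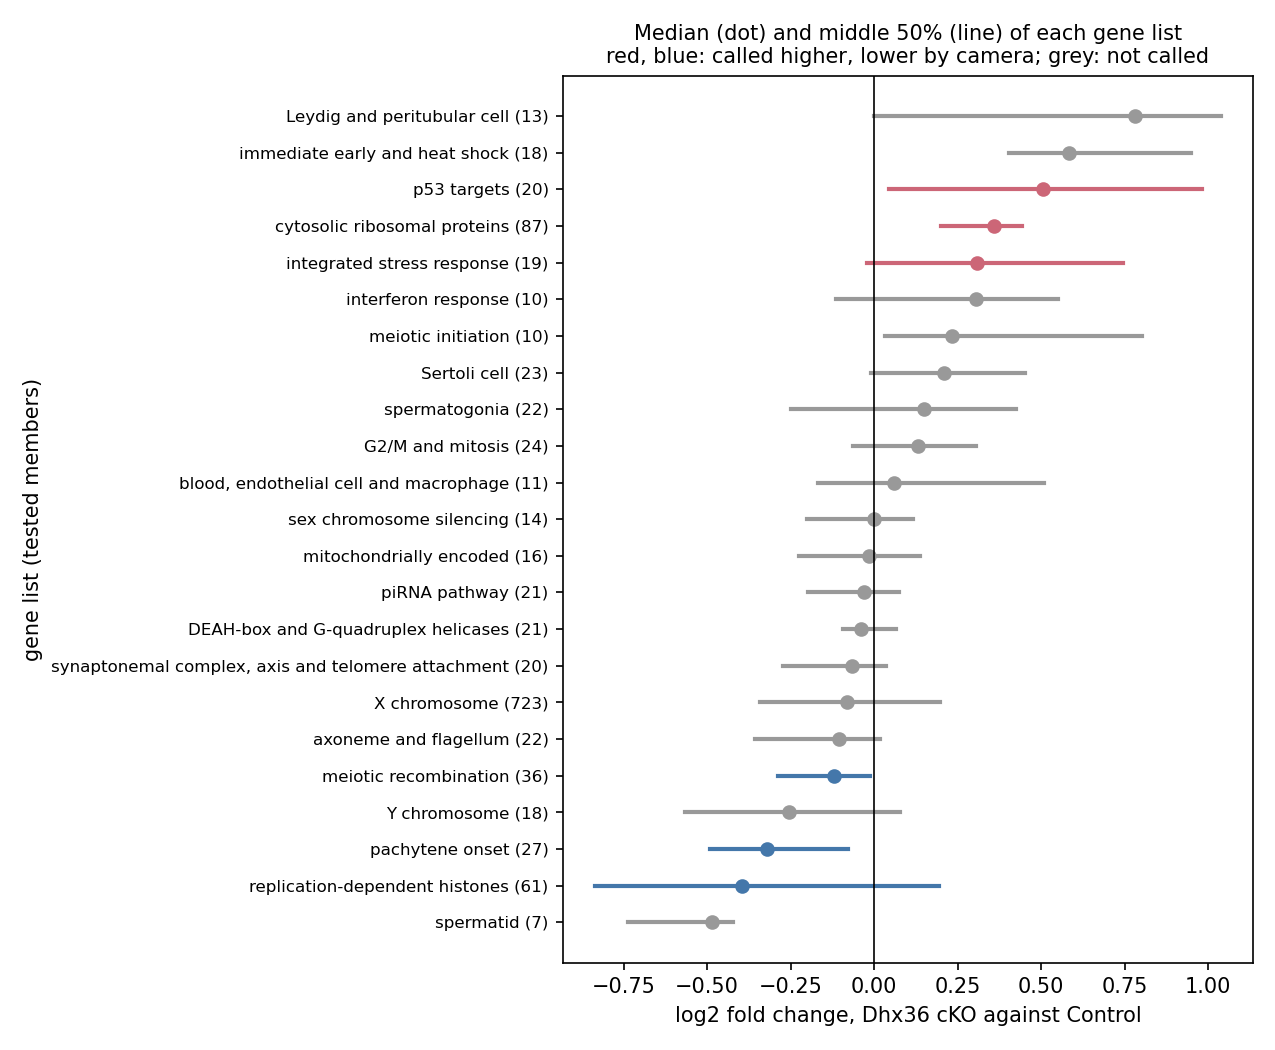
Dots show the median log2 fold change (Dhx36 cKO against Control, n = 2 each) of the tested members of 23 gene lists and lines their middle 50%; red and blue mark lists called higher and lower by camera with a preset correlation, grey those not called. Cytosolic ribosomal proteins (median 0.36) and p53 targets (0.50) lie among the lists called higher, and replication-dependent histones (−0.40) and pachytene onset (−0.32) among those called lower. None of the 6 was called with an estimated correlation, a test that also missed a simulated raised list.

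Markers of earlier germ cells included genes that changed, though neither list was called. Rec8, a meiotic cohesin gene, rose to 11.6 and 10.8 CPM from 3.30 and 5.33 CPM (log2 fold change 1.38, SE 0.25) and was the 1 called member of 10 on the meiotic initiation list (median 0.23, camera adjusted p = 0.175; 1 higher and 0 lower adjusted over the list alone). Stra8, at 0.91 (adjusted p = 0.0962), did not pass the test; the Cre allele lies in this gene. Among 22 spermatogonial markers Kit, a receptor gene of differentiating spermatogonia, rose by 1.03 (SE 0.12) and Dnmt3b by 0.69, while Gfra1, a marker of undifferentiated spermatogonia, fell by 1.23 on the log2 scale. The spermatogonia list had a median of 0.15 and was not called (camera adjusted p = 0.459; 5 higher and 2 lower adjusted over the list alone). Of 7 tested spermatid markers 0 passed the test, among all genes or adjusted over the list alone (median −0.48, camera adjusted p = 0.108). That list had a median of −0.15 without Dhx36 cKO replicate 2. It was called lower without Dhx36 cKO replicate 1 (median −0.82, 3 of 8 fell, adjusted p = 0.0376, and adjusted p = 0.689 with an estimated correlation) and with GC correction and the replicate block together (median −0.55, adjusted p = 0.0281).

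Among somatic cell markers, Col1a1, Col1a2 and Dcn stood highest in Dhx36 cKO replicate 1, while Myh11 and Ctsl changed in both Dhx36 cKO libraries. Col1a1, a fibrillar collagen gene, stood at 74.6 CPM in Dhx36 cKO replicate 1, 12.5 in Dhx36 cKO replicate 2 and 15.9 and 26.6 in Control, and Col1a2 at 61.8, 5.23, 14.2 and 20.4 CPM in the same order. Dcn stood at 16.2 and 1.23 CPM in Dhx36 cKO replicates 1 and 2. Myh11, a smooth muscle myosin gene, fell from 5.12 and 6.48 CPM to 2.57 and 1.43 CPM (log2 fold change −1.53) and was the 1 called member of 13 on the Leydig and peritubular cell list. That list had a median of 0.78 but a camera direction of lower (adjusted p = 0.834), so median and test differed in sign; adjusted over the list alone 0 were higher and 2 lower. It was called lower without Dhx36 cKO replicate 1 (median −0.86, 0 of 14 rose and 8 fell, adjusted p = 0.011, and adjusted p = 0.743 with an estimated correlation). It was called higher without Dhx36 cKO replicate 2 (median 1.41, adjusted p = 0.0364, and adjusted p = 0.686 with an estimated correlation). Ctsl rose from 120 and 106 CPM to 191 and 155 CPM (log2 fold change 0.61) as the 1 called member of 23 Sertoli cell markers (median 0.21, camera adjusted p = 0.126; 1 higher and 0 lower adjusted over the list alone). The Sertoli list had a median of 0.04 without Dhx36 cKO replicate 1. It was called higher without Dhx36 cKO replicate 2 (median 0.37, adjusted p = 0.0119, and adjusted p = 0.686 with an estimated correlation). None of the 11 blood, endothelial cell and macrophage markers passed the test, among all genes or adjusted over the list alone (median 0.06, camera adjusted p = 0.887).

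Among the other lists, Dhx15, a splicing helicase gene, rose by 0.71 and Dhx34 fell by 0.56 on the log2 scale, out of 21 DEAH-box and G-quadruplex helicase genes (median −0.04, camera adjusted p = 0.887; 2 higher and 1 lower adjusted over the list alone). The heat shock gene Hspa1b rose by 1.26 as the 1 called member of 18 immediate early and heat shock genes, of which 17 lay above 0 (median 0.58, camera adjusted p = 0.115; 1 higher and 0 lower adjusted over the list alone). Without Dhx36 cKO replicate 1 that median turned to −0.06, with 4 members higher and 5 lower. The list was called higher without Dhx36 cKO replicate 2 (median 1.06, adjusted p = 0.00138, and adjusted p = 0.686 with an estimated correlation) and without Control replicate 2 (median 1.07, adjusted p = 0.0376, and adjusted p = 0.98 with an estimated correlation). Dnah9, a dynein heavy chain gene, rose by 1.45 as the 1 called member of 22 axoneme and flagellum genes (median −0.10, camera adjusted p = 0.25; 1 higher and 1 lower adjusted over the list alone), a list that fry called lower (adjusted p = 0.0334). Of 723 genes on the X chromosome 4 rose and 20 fell (median −0.08, camera adjusted p = 0.115; 3 higher and 11 lower adjusted over the list alone), and of 18 on the Y chromosome 0 rose and 1 fell (median −0.25, camera adjusted p = 0.165; 0 higher and 1 lower adjusted over the list alone). The X list was called lower without Dhx36 cKO replicate 1 (median −0.13, 78 rose and 154 fell, adjusted p = 0.0361, and adjusted p = 0.689 with an estimated correlation). No member passed the test over all genes in the lists of the piRNA pathway (21 genes, median −0.03, camera adjusted p = 0.69), interferon response (10 genes, 0.30, 0.423), G2/M and mitosis (24 genes, 0.13, 0.194), sex chromosome silencing (14 genes, 0.00029, 0.753) and mitochondrially encoded genes (16 genes, −0.02, 0.703). The mitochondrial list was called lower without Dhx36 cKO replicate 2 (median −0.67, adjusted p = 0.017, and adjusted p = 0.686 with an estimated correlation). Without Dhx36 cKO replicate 1 its median was 0.28. Adjusted over the list alone, 1 sex chromosome silencing gene was higher and 1 lower, and 0 members of the other 4 lists passed. Of 4 tested genes from the literature on DHX36 targets, Gnai2 at 0.35, Trp53 at 0.20, Yy1 at −0.05 and Plau at 1.39 (adjusted p = 0.15), 0 passed the test, and the list was too small for a list test.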

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

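Counts of list members without Dhx36 cKO replicate 1, motif odds ratios with GC-corrected calls, and the gene lists and medians named under other observations with 1 library left out were chosen after the results were seen; the other alternatives were planned. The fall of Dhx36 kept its direction and its call under all 14 alternatives. The number of genes higher was 1814 with no filter on low counts, 927 with DESeq2, 816 with the replicate block and GC correction together, 30 at an adjusted p under 0.01, 1410 at an adjusted p under 0.1 and 147 at 2-fold or more, against 513. The number lower was 1168, 557, 617, 10, 1123 and 110 in the same order, against 330. Leaving out 1 library gave 14 to 3132 genes higher and 7 to 2832 lower; the lone sample of a group is then assumed to vary like the other group, and the Dhx36 cKO pair varied more than the Control pair. Of 57 called named genes, 5 kept their call without Control replicate 1, 9 without Control replicate 2 and 57 with either Dhx36 cKO library left out, and Dhx36, Gadd45a, Hist1h1d, Hist1h4f and Plk2 kept it in all 4 fits. The same-numbered replicates had a correlation of deviations of −0.036. This value over genes shows no pairing by number but cannot exclude one. The replicate block gave 508 genes higher and 324 lower, and 696 of the 843 calls were shared. Camera with an estimated correlation called 0 lists higher and 0 lower, and fry 1 and 1, against 3 and 3; leaving out 1 library gave 2 to 6 lists higher. None of the 843 called genes changed sign in any of these fits. The groups did not overlap in any of these 843 genes, so leaving out 1 library could hardly reverse a sign. The reversals below concern genes that were not called. They also concern lists that were not called, with the exception of meiotic recombination and S phase. For lists the direction is that of the test, which can differ from the sign of the median. With GC correction Clu was at −0.034, and at −0.027 with the block as well, the blood, endothelial cell and macrophage list at −0.070 and −0.039, and the mitochondrially encoded list at 0.091 and 0.039. The blood list had a median of 0.043 with a filter at a mean of 1 CPM, with camera lower, the piRNA list −0.0024 and the helicase list −0.027 with no filter, and the helicase list −0.040 with fry, whose direction was higher. With 1 library left out the log2 fold changes ran from −0.088 to 0.34 for Taf7l, −0.17 to 0.33 for Clu, −0.81 to 2.89 for Dcn, −0.75 to 1.82 for Col1a1, −1.71 to 1.84 for Col1a2, −2.44 to 3.06 for Lyz2, −0.94 to 0.31 for Cdh5, −0.29 to 0.25 for Vwf, −0.095 to 0.0014 for Yy1, −0.71 to 0.060 for mt-Rnr2, −0.014 to 0.28 for mt-Co1 and −1.07 to 0.088 for mt-Rnr1. List medians ran from −0.35 to 0.023 for meiotic recombination, −0.43 to 0.16 for the synaptonemal complex list, 0.021 to 0.16 for spermatogonia, −0.86 to 1.41 for Leydig and peritubular cells, −0.31 to 0.62 for the blood list, −0.15 to −0.021 for the piRNA pathway, −0.079 to −0.021 for the helicases, −0.058 to 1.07 for immediate early and heat shock genes, −0.12 to 0.095 for sex chromosome silencing, −0.67 to 0.28 for mitochondrially encoded genes and 0.0376 to 0.337 for S phase genes, which camera placed lower without Dhx36 cKO replicate 2 (adjusted p = 0.855). Within these ranges, the Leydig and peritubular list was at 0.95 and the mitochondrially encoded list at 0.19 without Control replicate 2. The estimated correlation was also used in the fits with 1 library left out, after these were seen. It left 0 of the list calls of those fits. The estimated correlation also missed the simulated list raised 1.3-fold, so these lost calls do not show that the lists are unchanged. For the changes with the filter, DESeq2, GC correction and the list tests the cause was not tested. Depth limits genes near 0.129 to 0.153 CPM, the level of 3 counts.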

Other observations

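The tests of other 5' TOP mRNAs, of an earlier average stage, of somatic cells, of base composition and of motifs with GC-corrected calls, the 9 gene lists named in these paragraphs and their values with 1 library left out were chosen only after the results were seen, so none is independent evidence.

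Sterol and fatty acid synthesis genes were higher: 7 of 32 tested rose and 0 fell (median log2 fold change 0.40). Acly, which makes cytosolic acetyl-CoA, rose from 184 and 190 CPM to 332 and 338 CPM (log2 fold change 0.84, SE 0.08), and Hmgcs1 and Insig1 of the sterol pathway rose by 0.70 and 0.69. Among 25 cell adhesion and actin linkage genes 11 rose and 0 fell (median 0.41), with Actn2 at 1.41, Itga6 at 0.91 and Ctnnb1, which encodes beta-catenin, at 0.55. Among 25 genes of mRNA decapping and decay 8 rose and 1 fell (median 0.13), with the decapping enzyme gene Dcp2 at 0.69, Upf2 at 0.76 and Upf3b at −0.53. All 3 lists were called by camera among the 9 (adjusted p = 4.28e-06, 0.000162 and 0.0046), and had adjusted p = 0.187, 0.167 and 0.167 with an estimated correlation. The decay list had a median of 0.219 without Dhx36 cKO replicate 1, and its median lay above 95.16% of random lists matched on expression, against 100% for the other two. Over the 9 lists 46 members passed the test, against 0 without Control replicate 1, 3 without Control replicate 2, 149 without Dhx36 cKO replicate 1 and 111 without Dhx36 cKO replicate 2.

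Among 14 snoRNA host RNAs 6 rose and 0 fell, led by Zfas1 at 1.49 and Snhg5 at 0.97 (median 0.46, camera adjusted p = 0.0046, and adjusted p = 0.167 with an estimated correlation); Rps3 is also on the ribosomal protein list. Among 20 clustered gamma protocadherins 6 fell and 0 rose (median −0.96, camera adjusted p = 8.48e-06, and adjusted p = 0.187 with an estimated correlation), with Pcdhga6 at −2.15 and counts that are uncertain because exons are shared. Annotated non-coding RNAs made up more of the genes that fell: 79 were lower and 25 higher, against 239 and 477 coding genes (Fisher's exact test across genes, odds ratio 6.29, 95% interval 3.85 to 10.6, p = 1.82e-16). Antisense RNAs are among them, and the strand setting of the counts is not given in the sources used here. Fisher's test treats genes as independent, which they are not. All 2956 tested non-coding RNAs had a median log2 fold change of −0.203, so the shift was not confined to called genes. Over tested genes the log2 fold change rose with transcript length (Spearman rho 0.176) and GC content (0.174). Fisher's test accounts for neither.

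Replication-dependent histone genes were lower, a call that rests on Dhx36 cKO replicate 1, without which the adjusted p was 0.135, and that had adjusted p = 0.894 with an estimated correlation. GC content bias as the whole cause is argued against by the histone median of −0.385 after GC correction (−0.66 to −0.279), which was −0.153 without Dhx36 cKO replicate 1, against −0.13 before correction, and −0.682 without Dhx36 cKO replicate 2. A smaller share of S-phase cells as the whole cause is argued against for all libraries together. There, 27 S phase genes had a median log2 fold change of 0.197 (95% bootstrap interval over genes, not over libraries, 0.0592 to 0.377, 1 rose). Camera gave them adjusted p = 0.0148, and adjusted p = 0.628 with an estimated correlation. Their median was 0.337 without Dhx36 cKO replicate 1. Without Dhx36 cKO replicate 2 it was 0.0376 (−0.172 to 0.0774), where the histone median was −0.567 (−0.832 to −0.257). The S phase interval there includes negative medians, so a smaller share of S-phase cells in Dhx36 cKO replicate 1 stays open. A lower yield of short RNAs without poly(A) tails stays open, since 164 small structured RNAs had a median of −0.245 (−0.371 to −0.16; 0 passed the test, camera adjusted p = 0.00137, and adjusted p = 0.167 with an estimated correlation), −0.149 without Control replicate 2, and cannot be told apart from a change in histone mRNA. An effect of the genotype stays open as well.

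Ribosomal protein genes were higher, though camera gave the list adjusted p = 0.894 with an estimated correlation. Short transcripts as the cause are argued against, since the list median lay above 100% of random lists matched on length and expression. Reads moved from pseudogenes to parent genes would lower the pseudogene counts. The 64 ribosomal protein pseudogenes had a median of 0.338 (0.265 to 0.425, 2 rose). Camera gave them adjusted p = 0.00137, and adjusted p = 0.377 with an estimated correlation. Without Dhx36 cKO replicate 2 that median was 0.167 (−0.00273 to 0.313). Pseudogenes are near-identical to their parent genes, so their counts may hold parent reads and this test cannot decide. A set of 20 other 5' TOP mRNAs shares a translation control motif with ribosomal protein mRNAs. Fau and Rack1, whose products are parts of the small ribosomal subunit, are among the 20, so the set is not free of ribosomal proteins. Its median lay above 99.99% of matched random lists. Of its members 4 rose, with Eef1a1 at 0.62 and Eef2 at 0.53 (camera adjusted p = 9.58e-05, and adjusted p = 0.167 with an estimated correlation). A shared rise of 5' TOP mRNAs is therefore a candidate explanation, as a hypothesis only. How multi-mapped reads were counted was not tested.

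Pachytene onset genes were lower and several early germ cell genes higher. More somatic cells in Dhx36 cKO replicate 2 are argued against: without Dhx36 cKO replicate 1 the pachytene onset list was still called, at a median of −0.419 (adjusted p = 0.689 with an estimated correlation), while 48 somatic markers had a median of −0.145 (−0.415 to 0.0409), below the 0.324 that such a dilution would need at the least while germ cells are the majority. In Dhx36 cKO replicate 1, the library with more collagen RNA, they stay open. Without Dhx36 cKO replicate 2, 52 somatic markers had a median of 0.468 (0.267 to 0.753) and the pachytene onset median was −0.228. Dilution would there need a rise of at least 0.197 if germ cells were a bare majority. At the purity in the labels, 97% or 95% for this library, it would need a larger rise, which was not computed. An earlier average stage of the sorted Dhx36 cKO cells cannot be told apart from other regulation of these genes at the same stage, since the lists that show the pattern are the ones that would measure the stage. The undifferentiated marker Gfra1 fell by 1.23.

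As a hypothesis, direct targets of DHX36 may hold G-quadruplex motifs, here 4 runs of at least 3 guanines with loops of up to 7 bases. Models of being called on motif, UTR length, GC content and expression numbered 8, with p adjusted over the 8. Of 474 genes called higher 21.3% had a motif in the 3' UTR, against 11.8% of uncalled genes (adjusted odds ratio 1.64, 1.28 to 2.09). The Wald test over genes (n = 474 called and n = 13098 uncalled) gave p = 7.82e-05 and an adjusted p = 0.000626. With GC-corrected calls the odds ratio was 1.53 (1.16 to 2.03, adjusted p = 0.0122). In the 5' UTR the odds ratio was 1.36 (1.03 to 1.80) but missed the threshold after adjustment (adjusted p = 0.08) and was 1.16 (0.836 to 1.61) with GC-corrected calls. For genes called lower it was 0.717 (0.372 to 1.38) in the 5' UTR and 1.02 (0.636 to 1.63) in the 3' UTR. The same motif with cytosines, which forms no RNA G-quadruplex, had an odds ratio of 1.27 (0.998 to 1.62) in the 3' UTR and 0.873 (0.64 to 1.19) in the 5' UTR of genes called higher. The interval for the cytosine motif overlaps that for the guanine motif, so base composition stays open in the 3' UTR. These models treat genes as independent, which they are not.

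Passenger alleles near the edited genes stay open: 2 called genes were among the 50 tested neighbours of Dhx36 and 3 among the 50 of Stra8, against 4.51% of other genes (odds ratio 1.11, 0.353 to 2.7). The 4 libraries allow 3 splits into pairs, too few for a share under 0.05. The real split called 843 genes. It was the only 1 of the 3 splits to give as many, and the highest of the others was 1.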
